A study of Mus musculus and Pogona vitticeps with 1200 samples.

How the data were processed

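Strips of 70 µm were cut from 14 µm coronal sections of 1 mouse brain and 1 lizard brain at 5 angles (9, 45, 81, 117 and 153°, the first to the fifth), and each strip was sequenced as polyadenylated RNA, per the labels. The deposited files are 15 tables of whole-number counts per gene and strip, 1 per plate, with no normalization. Neither the labels nor the tables say which program made the counts or whether molecules or reads were counted. The submitters' processing notes name the build mm10 for both organisms and no lizard build. Of the table columns, 1200 matched a sample and 240 matched none and were not used. The mouse tables held 24378 genes and 92 spike-in (ERCC) rows, and those of the lizard held 18579 genes, 92 spike-in rows and 17 other control rows. Control rows took 3.16% of mouse and 11.0% of lizard counts and were left out of all totals. No lizard row had the symbol of a mitochondrially encoded gene of the list, and 1126 lizard genes had only an identifier. No pair of strips had identical counts.

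The sections had 136, 148, 148, 152 and 136 strips in the mouse and 80, 96, 112, 104 and 88 in the lizard, in the order of the angles. Strips of a section were put in 1 order by series number and then strip number, an order that is assumed, since the labels do not say how the series of a section follow each other. Across the joins between series, the correlation of neighbouring strips was furthest under its median within the section in the lizard section at 45° (−0.074 against 0.228) and the mouse sections at 153° (0.104 against 0.301) and 9° (0.200 against 0.319), and furthest above it at a join of the mouse section at 117° (0.499 against 0.291). The join in the lizard section at 45° was close to the median of strips at least 20 apart (−0.087). At the join of the mouse section at 153°, 0.813% of the neighbouring pairs within the section were lower, against 1.32% in that lizard section. This mouse join lay above the median of strips at least 20 apart (−0.057). The strips kept for the tests (below) were unbroken, 125 over 8.75 mm in this mouse section and 78 over 5.46 mm in that lizard section. In the mouse section they ran from position 6 to 130. Exchanged series, or in the mouse 1 turned series, would put strips under the depth minimum inside the tissue, so these values argue against them. Whether 1 series of the lizard section was turned stays uncertain, and the low correlations at the joins are unexplained. The labels do not say from which side strips were numbered. The section is the replicate, with 5 per organism from 1 brain, and no test between organisms was possible. In the spline test the strips of 1 section were the units. Strips with at least 10% of the median total of their section were kept for the spline and list tests (642 of 720 in the mouse, 394 of 480 in the lizard). Median gene counts per kept strip were 263920, 206147, 256323, 228482 and 214258 in the mouse sections at 9, 45, 81, 117 and 153°, and 188673, 172971, 204347, 203143 and 247856 in the lizard sections. Genes with a mean of at least 1 count per strip in every section were tested (11150 and 10392).

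The tests, the gene lists and the rule for named genes were fixed before the data were examined. Patterned genes were found with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling) as a natural cubic spline of strip position with 8 degrees of freedom, fitted in each section on its own. The fitted range was log2 of the fitted maximum over the minimum between the 5th and 95th percentiles of strips, and was not printed as a fold for genes absent from long stretches. For these the share of the summed CPM in the richest 10% of strips was given. The shift of a gene was its count-weighted mean position minus that of all counts, fitted over 5 sections with limma 3.58.1 (with trend) to the cosine and sine of the angle without an intercept, which leaves 3 residual degrees of freedom. The main axis was the first principal direction of the fitted shifts, with its positive end at the median of the pallial list. The spread ratio was log2 of the root mean square distance from the centre of all counts over that of all counts, tested with limma as a mean over 5 sections. All tests were two-sided or F tests, and p-values were adjusted by Benjamini-Hochberg over genes with a threshold of 0.05.

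The 18 lists covered cell types, regions, immediate early genes and mitochondrially encoded genes, and were matched by symbol with case ignored. No gene of the mitochondrially encoded or erythroid list could be tested in the lizard. For lists with at least 3 tested members, the mean pairwise correlation of log2(CPM + 10) across strips, centred in each section, was placed among 10000 random lists matched on abundance, and lists above the 95th percentile were counted. Genes with the same symbol in both organisms were compared by Pearson's and Spearman's correlation with 10000 permutations of the pairing. Among genes with a mean of at least 5 counts per strip, the rule named the 5 largest shifts toward each end, the 5 narrowest and the 5 widest genes past the threshold and the 5 patterned genes with the largest fitted range, and then 2 to 4 members of each list by mean count. Genes named outside it are said to be chosen after their values were seen. Mouse coordinates are those of GENCODE M21 on GRCm38.

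Alternatives were other normalizations (DESeq2 1.42.0 size factors), the DESeq2 likelihood ratio test, gene minimums of 5 and none, splines with 4 and 15 degrees of freedom, series number as a covariate, no strip minimum, equal strip weights, strips above the minimum only, limma without trend, a pseudocount of 1, rank correlation, each section reversed in turn and each section left out in turn. After the count of 0 displaced genes was seen, all 16 combinations of reversed sections were tried, along with scaling to the spike-ins. Equal weights limited to strips above the minimum were added after the count with equal weights had been seen. The reversal shown for the lizard was also chosen after its counts were seen. Sections 117 and 153 together gave 308 genes and were taken first, and section 153 alone, which gave 188 and was among the alternatives fixed beforehand in both organisms, took their place.

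The tests were tested on simulated data with the real means and depths. The simulated counts had the same dispersion for every gene, no added spread between sections and no correlation between neighbouring strips. The calls below thus do not give the error rate or the power in the real sections. A spline peak of 1 on the log2 scale in the section at 9° was called for 85 of 100 mouse and 42 of 100 lizard genes, and 1 of 0.5 for 14 and 1. A shift of 200 µm was called for 27 of 100 mouse and 83 of 100 lizard genes, and a spread change of −0.2 for 100 of 100 in both. Of unchanged genes (10950 in the mouse and 10192 in the lizard) 3, 0 and 4 mouse genes and 6, 6 and 7 lizard genes were called by the 3 tests. Of 20 simulated lists with a shared factor 20 were above the 95th percentile in each organism, and of 20 without 1 and 3. The correlations across organisms were not tested on simulated data. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.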

Results

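Polyadenylated RNA was measured along thin coronal sections of 1 mouse brain and 1 brain of the bearded dragon Pogona vitticeps, an agamid lizard. Each 14 µm section was cut into parallel 70 µm strips, and each strip was made into its own library. In each organism 5 sections were cut, the first at 9° and each next one 36° further, so that every gene was profiled along 5 directions in the plane. The mouse gave 720 strips and 145737103 counts in genes. The lizard gave 480 strips and 82910997 counts. A total of 642 mouse strips and 394 lizard strips held at least 10% of the median total of their section, with 20242 to 523264 and 15938 to 553456 gene counts each. The section was the replicate for the shift and spread tests (n = 5 per organism), and the 5 sections differed in cutting angle. The spline test was fitted to the strips of each section, so its p-values measure the spread between strips. All sections of an organism came from 1 brain, so p-values measure the spread within that brain and not between animals.

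The first question was which genes varied in abundance along the sections at every angle. In the mouse the largest fitted ranges belonged to Ttr and Kl, which are abundant in the choroid plexus, and to Avp, Oxt and Pmch, which encode the hypothalamic peptides vasopressin, oxytocin and melanin-concentrating hormone. The richest 10% of strips for each gene held 77.5% ± 10.1 (SD, n = 5 sections) of the summed abundance of Ttr, 71.5% ± 9.16 of Kl, 82.9% ± 5.33 of Avp, 83.4% ± 3.09 of Oxt and 96.9% ± 1.46 of Pmch. The median of the 6761 mouse genes with a mean of at least 5 counts per strip was 17.5%. Ttr reached 24692 ± 4725 CPM (counts scaled to the same total in every strip) in those strips, against 3630 ± 206 CPM for all counts of a section pooled. In all, 3219 of 11150 tested mouse genes were patterned, that is, their spline of strip position passed edgeR's quasi-likelihood test at an adjusted p under 0.05 in each of the 5 sections. The fitted range exceeded 2-fold in every section for 1433 of them, while 3104 genes passed in no section. Ttr lies on chromosome 18 at 20665280 to 20674321 of GRCm38, Avp and Oxt lie near each other on chromosome 2 at 130580620 to 130582554 and 130576173 to 130577054, and Pmch lies on chromosome 10 at 88091072 to 88092375. In all, 1207 of 24378 mouse rows and 3895 of 18579 lizard rows are marked as 1 of several loci. Only rows of Hba-a2 in the mouse and MYOF_loc1 in the lizard are named below. A marked name does not match the plain symbol of a list gene, so such rows were not matched to the lists.

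Most lists had nearly all of their members patterned in the mouse. All tested members passed in 5 sections for oligodendrocytes and myelin (12 of 12), astrocytes (12 of 12), choroid plexus (7 of 7), ependyma and motile cilia (6 of 6), thalamus (10 of 10), striatum and subpallium (9 of 9), GABAergic neurons (11 of 11) and the mitochondrially encoded genes (13 of 13). The count was 11 of 12 for pallial excitatory neurons and 7 of 8 for the hypothalamus. It was lower for microglia (6 of 11), blood vessels (5 of 10), meninges (6 of 8) and immediate early genes (5 of 8). Mbp, a structural protein of myelin, had a fitted range of at least 2.80 on the log2 scale in each section. Ranges were smaller for the astrocyte genes Slc1a2, a glutamate transporter (0.62), and Aldoc (0.48), and for the microglial gene C1qa (0.62). Among the members followed under other settings, Aldoc, Cx3cr1, Vtn, Acta2, Col1a2, Igf2, Rsph1, Tac2, Lrrc55, Lhx6, mt-Co1, mt-Co2, mt-Co3 and mt-Atp6 did not pass with a spline of 4 degrees of freedom, Cx3cr1, Rgs5 and Lhx6 did not with 1 of 15, and mt-Co1, mt-Co3 and mt-Atp6 did not without a strip minimum. Cx3cr1 and Rgs5 did not pass with the series number as a covariate, nor did Cx3cr1 with DESeq2 size factors or without a gene filter.

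**Figure D1:**
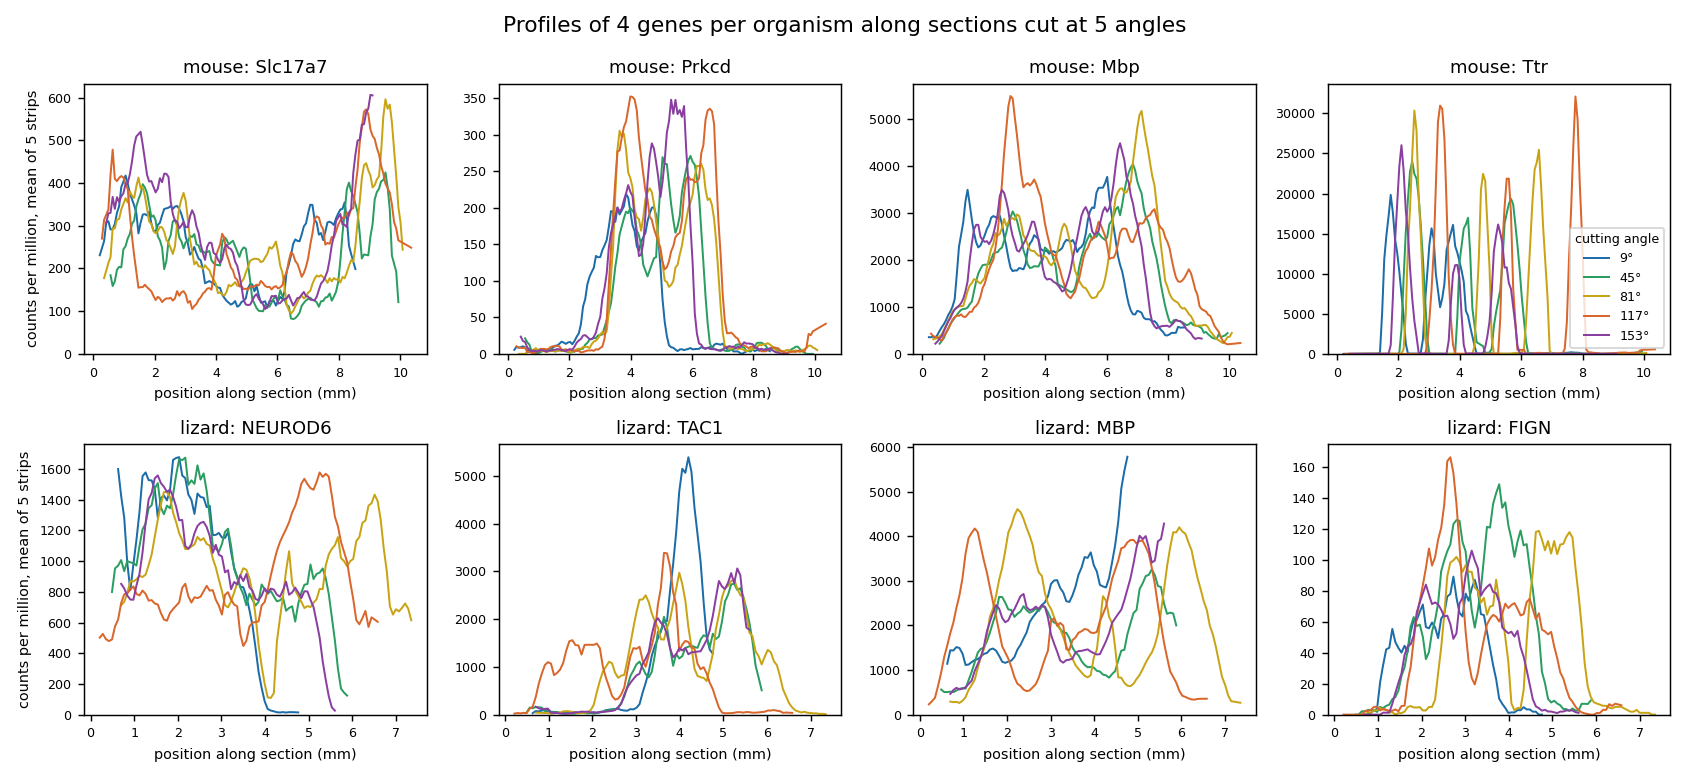
CPM along each section, as a running mean of 5 strips, for 4 mouse genes (top) and 4 lizard genes (bottom), with position in mm from the first strip and 1 line per cutting angle. Prkcd lay in a central stretch of every mouse section and Ttr in narrow peaks. In the lizard the richest 10% of strips held 35.7% of the summed abundance of TAC1. The share was 18.4% for NEUROD6, close to the median gene (18.4%).

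The second question was how far each gene's RNA spread from the centre of all RNA, as the ratio of the root mean square distances, which does not depend on the direction in which strips were numbered. The narrowest mouse genes were Pmch, at −1.45 ± 0.61 on the log2 scale (SD, n = 5; adjusted p = 3.6e-06), Prkcd (−1.08 ± 0.05; 1.3e-14), Tcf7l2 (−1.08 ± 0.05; 4.5e-14), Oxt (−0.90 ± 0.33; 9.1e-07) and Plekhg1 (−0.78 ± 0.03; 1.1e-13). Prkcd and Tcf7l2, a protein kinase C and a transcription factor abundant in the thalamus, thus spread 0.472 and 0.473 times as far as all RNA. The widest were Slc30a3 (0.31 ± 0.01; 1.0e-11), which loads zinc into synaptic vesicles of cortical neurons, Plxnd1 (0.29 ± 0.04), Nov (0.28 ± 0.06), Ddit4l (0.26 ± 0.06) and Rprm (0.26 ± 0.04). Over all genes, 3091 were narrower and 2881 wider than all RNA by limma's moderated test at an adjusted p under 0.05. Prkcd lies on chromosome 14 at 30595354 to 30626210, Tcf7l2 on chromosome 19 at 55741820 to 55933654 and Slc30a3 on chromosome 5 at 31086106 to 31108237. The count of wider genes was 186 when every strip was given the same weight, which includes strips with very few counts, and 2186 when this was limited to strips above the depth minimum. Under the first of these weights Plekhg1 no longer passed (−0.41; adjusted p = 0.16).

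Genes of deep or lining tissues were narrow as groups in the mouse. All 10 tested thalamic genes were narrower than all RNA, with a list median of 0.658 times the spread, as were all 7 choroid plexus genes (0.748; Ttr −0.48 ± 0.07, Enpp2 −0.29 ± 0.03), all 6 ependymal genes (0.763; Mia −0.35 ± 0.06) and 7 of 8 hypothalamic genes (0.692). Cartpt was the exception in the last list (0.03 ± 0.04; adjusted p = 0.071), and it passed as wider without the section at 81° (0.04; 0.0041). All 12 oligodendrocyte genes were narrower with little spread between sections (0.824; Mbp −0.27 ± 0.02, Mobp −0.31 ± 0.03, Mal −0.28 ± 0.01). Both tested hippocampal genes (Spink8 −0.45 ± 0.14, Zbtb20 −0.13 ± 0.07) and both tested habenular genes (Tac2 −0.19 ± 0.09, Lrrc55 −0.07 ± 0.03) were narrower, as was Ddc, the only tested monoaminergic gene (−0.30 ± 0.09). Adjusted over the list alone, these counts were unchanged, except that 1 hypothalamic gene, Cartpt, was also called wider. When all strips weighed alike, Enpp2 and Rarres2 fell short of the threshold (adjusted p = 0.062 and 0.34) and Zbtb20 turned to 0.04 (adjusted p = 0.71).

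Pallial excitatory neuron genes were wide in the mouse, with 11 of 12 wider and 1, Neurod6, narrower (−0.08 ± 0.01) and a list median of 1.14 times the spread of all RNA. Mef2c reached 0.21 ± 0.03, Nrgn 0.20 ± 0.03, Camk2a 0.19 ± 0.02 and Slc17a7, the vesicular glutamate transporter of cortical neurons, 0.16 ± 0.02. Immediate early genes, which are transcribed after neuronal activity, were wider for 7 of 8 members (Egr1 0.16 ± 0.03, Nr4a1 0.15 ± 0.02, Junb 0.14 ± 0.02, Arc 0.12 ± 0.04). Of 11 GABAergic genes 4 were wider, namely Vip (0.26 ± 0.04), Npy (0.17 ± 0.05), Lhx6 and Sst (0.04 ± 0.04), and 4 narrower, namely Pvalb (−0.16 ± 0.05), Gad2 (−0.09 ± 0.01), Gad1 (−0.05 ± 0.03) and Slc32a1. Of 9 striatal genes 2 were narrower, Six3 (−0.45 ± 0.07) and Tac1 (−0.08 ± 0.09; adjusted p = 0.0079), and none passed as wider. Penk (0.06 ± 0.11) and Ppp1r1b (0.05 ± 0.14) did not pass, but did so without the section at 9° (0.10 each). Neurod6, Vip, Lhx6, Pvalb, Slc32a1 and Six3 were named after their values were seen. Counts adjusted over the list alone were the same for these 4 lists. When all strips weighed alike, Mef2c, Npy and the 4 immediate early genes with values above did not pass (adjusted p from 0.084 to 0.86), Lhx6 turned to −0.10, and Sst turned to −0.09, or to −0.01 over strips above the minimum. Slc32a1 did not pass with all strips weighed alike (adjusted p = 0.096). Tac1 (−0.02; adjusted p = 0.31) and Slc32a1 (−0.01; 0.35) did not pass with counts scaled to the spike-ins. Neither Tac1 nor Sst passed without limma's trend (adjusted p = 0.057 and 0.065), and Sst did not without the section at the fifth angle (0.051). Lhx6 did not pass with equal weights over strips above the minimum (0.02; adjusted p = 0.48).

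Among other cell types the mouse values lay closer to those of all RNA. Of 12 astrocyte genes 8 were narrower (S100b −0.12 ± 0.02) and 1, Slc1a2, wider (0.09 ± 0.01). Glul did not pass by limma's test, but did so as wider when all strips weighed alike (0.08, adjusted p = 0.019). It also did with equal weights over strips above the minimum (0.07, 6.9e-05) and without the section at the fifth angle (0.02, 0.029). Microglial genes were narrower for 5 of 11 (Ctss at −0.09 ± 0.01, C1qa, C1qb and Tyrobp among them) and wider for 1, Cx3cr1 (0.02 ± 0.01), which did not pass without the section at 45 or 81° or that at the fourth angle. Blood vessel genes were narrower for 4 of 10 (Bsg −0.04 ± 0.01, Itm2a, Ly6c1 and Rgs5) and wider for 1, Acta2 (0.13 ± 0.08). Meningeal genes were narrower for 2 of 8 (Apod −0.17 ± 0.04, Dcn −0.09 ± 0.09) and wider for 2 (Col1a2 and Nupr1), or 3 adjusted over the list alone (with Slc6a13). Igf2 did not pass, but did so as narrower without the section at 9° (−0.09; adjusted p = 0.0021), over strips above the minimum (−0.09; 0.0082) and with counts scaled to the spike-ins (−0.10; 0.010), and as wider when all strips weighed alike (0.33; 0.0030), as did Ptgds (0.37; 0.010). Adjusted over the list alone the other 3 lists gave the same counts. C1qb, Tyrobp, Ly6c1, Rgs5, Acta2, Col1a2, Nupr1 and Slc6a13 were named after their values were seen, as was mt-Nd6. The only tested gene of the erythroid list, Hbb-bs, did not differ detectably (−0.03 ± 0.23, adjusted p = 0.68), but passed as narrower without the section at 9° (−0.11, adjusted p = 0.033). Mitochondrially encoded genes were wider for 8 of 13 (mt-Atp6 0.03 ± 0.01, mt-Co3 0.02 ± 0.01) and narrower for 1, mt-Nd6 (−0.08 ± 0.02), also when adjusted over the list alone. S100b, Itm2a, Apod, Dcn and Tyrobp changed direction when all strips weighed alike, and C1qa, C1qb, Cx3cr1, Bsg, Ly6c1 and Nupr1 did not pass (adjusted p from 0.063 to 0.50). Over strips above the minimum C1qa and Ly6c1 did not pass with equal weights (adjusted p = 0.10 and 0.48), nor Cx3cr1, Col1a2 and Nupr1 with the weights as reported (0.10, 0.075 and 0.059). With counts scaled to the spike-ins Acta2, Col1a2, Nupr1 and Cx3cr1 did not (0.077, 0.42, 0.065 and 0.092). Nupr1 did not pass without the section at 9 or 45° (0.064 and 0.092) or without limma's trend (0.067) either.

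**Figure D2:**
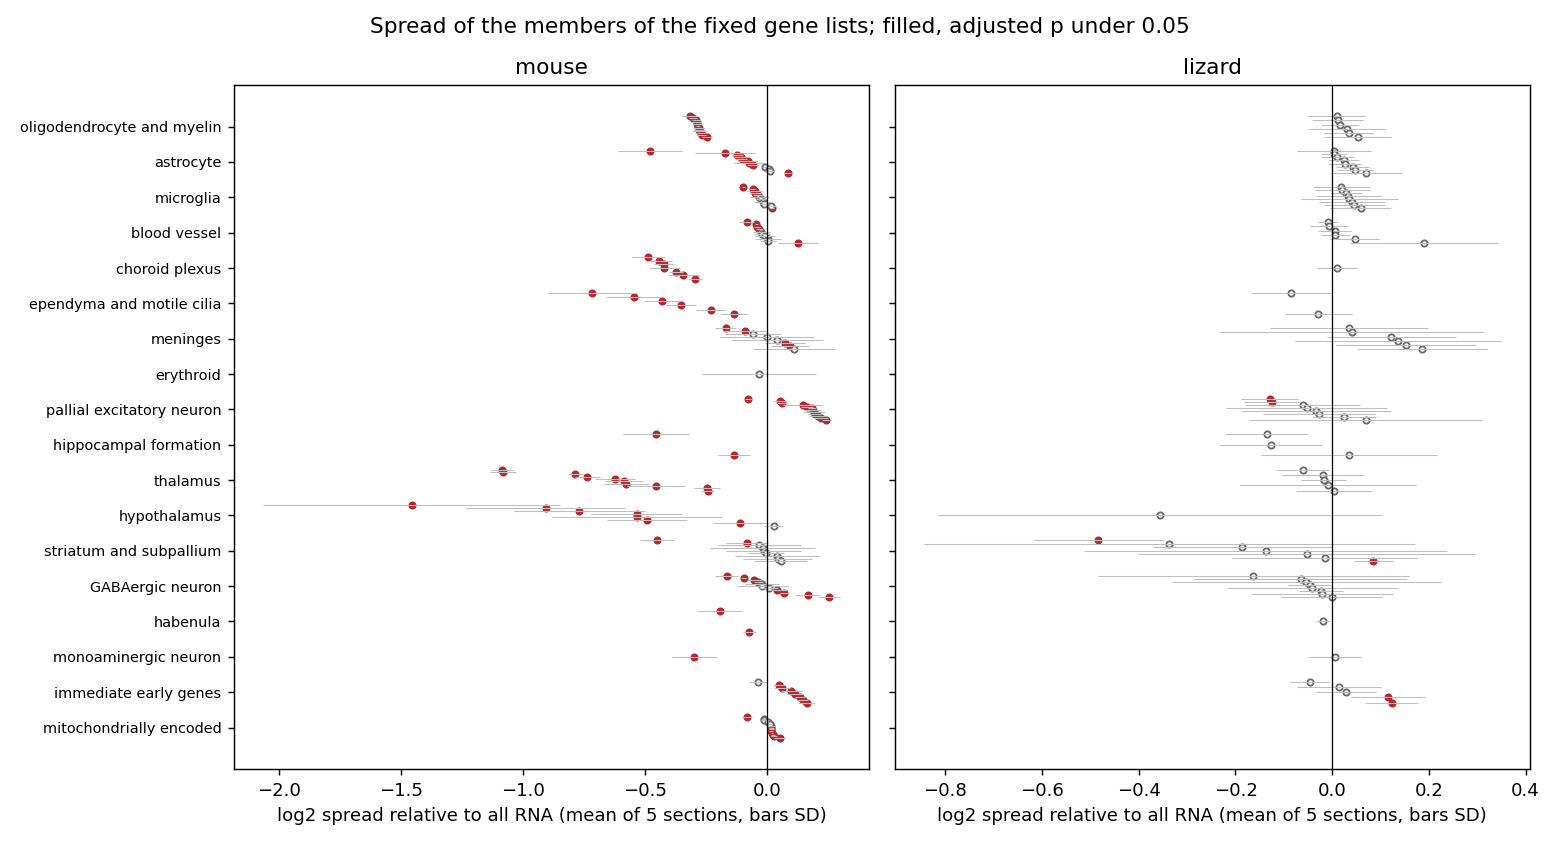
Mean log2 spread of each tested list member relative to all RNA in the mouse (left) and lizard (right), with horizontal bars for the SD between 5 sections; filled points passed limma's test at an adjusted p under 0.05. In the mouse the thalamic, choroid plexus and oligodendrocyte members lie left of 0 and 11 of 12 pallial members right of it; the horizontal scales differ between panels.

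In the lizard the largest fitted ranges belonged to FIGN, MMEL1, TAC3, TAC1 and SS2. TAC1 encodes the precursor of substance P, and the richest 10% of strips held 35.7% ± 7.13 of its summed abundance, at 3483 ± 1056 CPM against 1087 ± 142.9 for all counts of a section pooled. The same share was 47.2% ± 7.65 for SS2 and 31.3% ± 3.03 for FIGN, against a median of 18.4% over 6376 genes. In all, 785 of 10392 tested lizard genes were patterned in every section, 504 of them over more than 2-fold, and 3558 passed in no section. From the first to the fifth angle 1717, 3296, 4243, 4957 and 1830 lizard genes passed in the single section, with 60, 78, 96, 89 and 71 kept strips. The mouse sections gave 5319, 5035, 5992, 5696 and 4905. The lizard sections at 9° and at the fifth angle, with the fewest kept strips, thus limit the count over every section. Patterned members were 6 of 7 for striatum and subpallium (TAC1, PENK, SIX3 and DRD1 among them), 7 of 8 for pallial excitatory neurons, 5 of 6 for oligodendrocytes and myelin, 5 of 8 for astrocytes, 5 of 8 for GABAergic neurons, 2 of 6 for meninges (PTGDS and DCN), 2 of 5 for thalamus (SLC17A6 and RGS16), 2 of 5 for immediate early genes (ARC and BTG2), 1 of 3 for the hippocampal formation (FIBCD1), 1 of 6 for blood vessels (ACTA2, not passing with the DESeq2 test, a spline of 4 degrees of freedom or a minimum of 5 counts) and 0 of 8 for microglia. PENK, the enkephalin precursor, had a fitted range of at least 4.79 on the log2 scale in each section, and MBP of at least 1.63. ENPP2 and CARTPT, the only tested choroid plexus and hypothalamic genes, passed in all sections, while none of 2 ependymal genes and neither LRRC55 nor EN1, the only tested habenular and monoaminergic genes, did. With a spline of 4 degrees of freedom the astrocyte genes GLUL, SLC1A3 and GJA1 and the pallial gene CAMK2A did not pass. CAMK2A also did not with 1 of 15, with the series number as a covariate or without a gene filter, GLUL did not without a gene filter, and GJA1 did not with the DESeq2 test or a minimum of 5 counts. Without a strip minimum the count of patterned lizard genes was 2875.

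Fewer lizard genes differed in spread, 401 in all, 288 of them narrower and the rest wider, and the spread between sections was larger (median SD of the log2 ratio 0.0456 over genes, against 0.0250 in the mouse). The narrowest were FIGN (−0.65 ± 0.07; adjusted p = 3.0e-06), SNTN, a protein of ciliary tips (−0.62 ± 0.12), CDKN1C, a cyclin-dependent kinase inhibitor (−0.53 ± 0.06), CACNG4 (−0.49 ± 0.12) and MYOF_loc1, 1 of several loci of that name (−0.48 ± 0.15). The widest were NR4A2 (0.25 ± 0.13; adjusted p = 0.011), CNTNAP4 (0.24 ± 0.11; 0.0049), RASL11B (0.18 ± 0.11), CENPW (0.17 ± 0.10) and DOC2A (0.17 ± 0.12). Of 8 pallial genes 2 were narrower, SLC17A7 (−0.13 ± 0.06) and NEUROD2 (−0.12 ± 0.06), and none passed as wider. Of 5 immediate early genes 2 were wider, FOS (0.12 ± 0.06) and BTG2 (0.12 ± 0.08). Of 7 striatal genes GPR6 was narrower (−0.48 ± 0.13) and RGS9 wider (0.08 ± 0.04). SLC17A7, GPR6 and RGS9 were named after their values were seen. No member of the oligodendrocyte (MBP 0.01 ± 0.05), astrocyte, microglial, vascular, thalamic, meningeal or GABAergic lists passed over all genes. Adjusted over the list alone, the calls that were added included 3 meningeal genes (COL1A1, COL1A2 and OGN, the last chosen after its value was seen) and 1 vascular gene (ACTA2, 0.19 ± 0.15) as wider. Added as narrower were 2 of 3 hippocampal genes, a second striatal gene, 1 ependymal gene (RSPH1) and CARTPT. Without the section at 9° the counts were 661 narrower and 422 wider, and without any other section at most 182 and 75. Without it TAC1, PENK, DRD1, PVALB, GAD2, NPY, SLC32A1, RSPH1, ZBTB20 and CARTPT passed as narrower and ACTA2, COL1A1 and GJA1 as wider. Without the section at 45° NEUROD2, SLC17A7, FOS and BTG2 did not pass, without that at the fourth or that at the fifth angle FOS and BTG2 did not, without that at the fifth NR4A2 did not (adjusted p = 0.054), and RASL11B, DOC2A, CENPW and RGS9 did not without each of the 4 sections other than that at 9°. Without limma's trend those 4 genes and BTG2 did not pass (adjusted p from 0.056 to 0.089). With counts scaled to the spike-ins FOS and BTG2 did not (0.070 and 0.072), nor did BTG2 over strips above the minimum (0.069). When all strips weighed alike, only CACNG4 and MYOF_loc1 of the genes named with a call over all genes still passed, the others had an adjusted p from 0.0502 to 0.79, and RGS9 turned to −0.05. With equal weights over strips above the minimum NEUROD2, DOC2A and RGS9 did not pass (0.051, 0.051 and 0.078).

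The third question was whether genes lay off the centre of all RNA in a consistent direction. With strips in the order of their numbers, no gene passed limma's moderated F test in either organism (0 of 11150 mouse genes, 1013 at an unadjusted p under 0.05, and 0 of 10392 lizard genes, 634 at an unadjusted p under 0.05). Without limma's trend both counts were also 0, with 992 and 655 at an unadjusted p under 0.05. Adjusted over the list alone, 7 meningeal, 7 striatal, 2 GABAergic and 1 blood vessel gene passed in the mouse, and no list member in the lizard. Without the section at the fifth angle, 3234 mouse genes and 1.33% of the lizard genes passed, and with the order of its strips reversed 4303 and 188 did. The median shift of the 12 mouse pallial genes was −708 µm at 9°, −608 at 45°, −419 at 81°, 370 at the fourth angle and −617 at the fifth, and that of the 8 hypothalamic genes had the opposite sign at every angle (1041, 1128, 662, −675 and 1473 µm).

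With the section at the fifth angle reversed, 1737 mouse genes lay toward the end of the main axis set by the pallial list and 2566 toward the other. The following genes were named after their values were seen. Toward the pallial end lay Hbb-bs (1709 ± 66.8 µm, SE), then the rows Hba-a2_loc2 and Hba-a2_loc1, then Vip (1301 ± 67) and Lamp5 (1293 ± 50.6). Toward the other end lay Baiap3 (−1990 ± 71.4), Nts (−1889 ± 78.2) and Avp (−1848 ± 95.9). All 8 tested hypothalamic genes, all 9 striatal genes (Penk −852 ± 45.3, Tac1 −748 ± 48.5) and all 8 meningeal genes lay away from the pallial end, and 6 of 7 choroid plexus genes (Ttr 1158 ± 40.1) and 7 of 8 immediate early genes toward it, and adjusted over the list alone these counts were the same. All 12 pallial genes passed, but that list set the sign of the axis and is not evidence for its own side. In the lizard only 2 of the 8 pallial genes that set the sign passed toward that end and 1 passed away from it (median of the list 122.4 µm), so that the end is less well defined there. Of the 188 lizard genes 74 lay toward the pallial end, among them NR4A2 (1073 ± 51.4), and the rest away from it, among them MMEL1 (−1270 ± 69.1) and TAC1 (−1221 ± 81.3). There 6 of 7 striatal genes, or 7 adjusted over the list alone, and 5 of 8 GABAergic genes, the same adjusted over the list alone, lay away from the pallial end. With the lizard sections at the fourth and the fifth angle both reversed 308 genes passed, and without the section at the fourth angle 2108 did with that at the fifth reversed, against 29, 50 and 63 without the section at 9, 45 and 81°, so that the lizard files do not fix which sections ran the other way. The labels give no direction of numbering, and these p-values do not account for the choice of the reversed section. When all strips weighed alike no gene passed with that section reversed in either organism, and over strips above the depth minimum 3298 mouse genes and 156 lizard genes did.

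**Figure D3:**
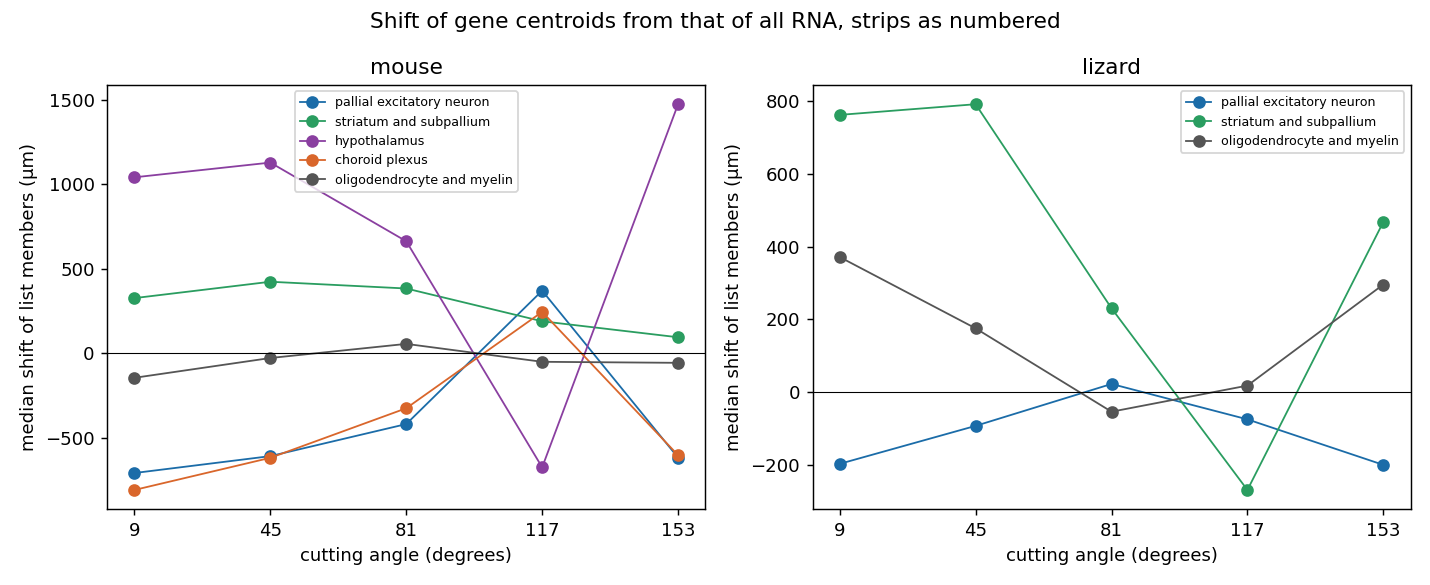
Median shift in µm of the members of 5 lists from the centre of all RNA at each cutting angle, with strips as numbered, in the mouse (left) and for the 3 of these lists with at least 3 tested members in the lizard (right). In the mouse the pallial and hypothalamic lists have opposite signs at every angle, and each has the sign at the fifth angle that it has at the first.

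Members of a list varied together along the strips in most lists. In the mouse all 14 lists with at least 3 tested members had a mean pairwise correlation above the 95th percentile of 10000 random lists matched on abundance, and in the lizard 9 of 11 did. The highest in the mouse were the oligodendrocyte list (0.869 ± 0.023, SD over 5 sections), choroid plexus (0.781 ± 0.030), thalamus (0.658 ± 0.055) and striatum and subpallium (0.658 ± 0.024), and in the lizard the oligodendrocyte (0.634 ± 0.059), meningeal (0.420 ± 0.066) and striatal (0.363 ± 0.018) lists. The pallial list reached 0.332 ± 0.043 in the mouse and 0.195 ± 0.056 in the lizard. The lizard thalamic list (0.052 ± 0.077, percentile 78.8) and blood vessel list (0.047 ± 0.043, percentile 78.6) did not exceed that level. The lizard hippocampal list (3 genes, 0.110 ± 0.108) fell to percentile 87.8 with values centred in each series. It fell to 92.96 without the section at the fifth angle and to 94.98 without that at 45°. The lizard immediate early list fell to 90.6 with a pseudocount of 1 and to 94.7 without the section at 81°. With strips under the depth minimum included, 7 mouse and 3 lizard lists exceeded the 95th percentile. The pallial list of both organisms (percentile 41.4 in the mouse and 3.41 in the lizard) and the lizard striatal list (41.2) were among those that did not.

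The last comparison set the organisms side by side over genes with the same symbol. Across 6633 such genes the spread ratios were almost unrelated (Pearson's r = 0.028, permutation p = 0.023; Spearman's rho = −0.020, permutation p = 0.10). The shifts along the main axis as numbered were weakly related across 6625 genes without the pallial list (r = 0.089; rho = 0.067; both with a permutation p of 0.0001, the smallest that 10000 permutations can give). Adjusted by Benjamini-Hochberg over these 4 correlations, the p was 0.030 for r and 0.10 for rho of the spread ratios and 0.0002 for both of the shifts. Genes are not independent replicates, and there was 1 brain per organism, so no difference between organisms was tested. The labels do not give the level of the sections, so those of the 2 organisms may hold different regions. In the lizard 1 hypothalamic and 1 choroid plexus gene could be tested, against 8 and 7 in the mouse. The spread correlation was 0.062 without the lizard section at 9°, 0.0070 without that at 81° (permutation p = 0.57), 0.0063 without that at the fourth angle (permutation p = 0.61) and 0.14 when all strips weighed alike. The shift correlation was −0.123 without the lizard section at 9°, 0.012 without that at 45° (permutation p = 0.31), 0.030 without that at 81° and 0.020 when all strips weighed alike (permutation p = 0.11). The main axis was set anew in each setting, and its sign by the pallial list. In the lizard the median shift of that list was only −199 to 23 µm over the angles. The sign of the shift correlation can thus turn with the axis, and a negative value need not mean a reversed relation.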

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

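The tests of the 3 patterns below, the scaling to spike-ins and the combinations of reversed sections among them, were chosen after the counts they address had been seen; the permuted strip orders and the reversal of 1 section at a time were not. Among 57 groups of 5 sections, 4 had 1 value far from the others, where chance gives about 1 in 20. The spread of Tcf7l2 in the mouse was −0.9856 at 9° and −1.1266 to −1.0906 at the other angles. In the lizard the section at 9° gave −0.0375 for DOC2A against 0.1902 to 0.2615, and −0.004 for CENPW against 0.1851 to 0.249. The median share of counts in mitochondrially encoded genes was 15.232% in the mouse section at 45° and 13.7619 to 14.123% in the others. Of 67 list genes measured in both organisms 2 had opposite spread in all sections, Slc17a7 (mean 0.165 in the mouse, −0.1291 in the lizard) and Neurod2 (0.0649 and −0.125), and these differences were not tested. The 9 marker rows of the lizard tables, which no comparison uses, held 4 counts in 3 of 480 strips.

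Genes patterned in every section exceeded what permuted strip orders gave. The real order was 1 of 21 orders, the only one with as many genes, with 3219 mouse genes against at most 2 in the others and 785 lizard genes against 0. This argues against calls from noise unrelated to the strip order. Permuting the strips also breaks any smooth technical drift along a section. The test thus cannot tell position in the tissue from such drift.

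In the mouse, limma called 0 displaced genes with strips as numbered (1013 at an unadjusted p under 0.05) and 4303 with the section at the fifth angle reversed. Across 6031 genes the shifts in that section correlated at −0.8877 with those predicted from the other 4. This mirror image argues against another level of the brain. It goes with strips numbered from the opposite side or a section turned over in the plane. A wrong order of the series of that section, whose join had a low correlation, was not tested. Under the 12 distinct assignments of the angles, each with its best of 16 combinations of reversed sections, the real one gave 4303 genes, the largest count (1 of 12), and the highest other 3613, and 12 are too few for a share under 0.05. No biological explanation was tested.

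In the lizard, limma likewise called 0 displaced genes as numbered (634 at an unadjusted p under 0.05). Shifts in the section at the fifth angle correlated at −0.4248 with those predicted from the other 4, and from the first 3 sections at −0.7622 for the fifth and −0.1372 for the fourth, so that reversal of 1 or of both sections cannot be told apart, since the value for the fourth, and that for the fifth from the other 4, fall short of −0.5. With both reversed 308 genes passed, while 3 of the 12 angle assignments, the real one included and each with its best combination, gave as many or more and the highest other 607, and 12 are too few for a share under 0.05. No biological explanation was tested.

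Fewer genes were narrower or wider in the lizard (401) than in the mouse (5972). Mouse counts thinned to the lizard section totals still gave 4656 genes among 9386 tested, 11.61 times the lizard number, which argues against depth. Scaling lizard counts to the spike-ins gave 407 genes, 1.015 times the count without. This cannot decide on steps in yield along a section, since the scaling changes a gene's counts and all counts of a strip alike. The spread ratio varied more between lizard sections, by 1.747 times the mouse SD at matched mean count per strip (1.589 to 2.761 over deciles). That larger spread could limit the calls. Lizard sections held fewer strips, so genes matched in this way had fewer counts per section. The SD also holds differences between the cutting angles. Whether that spread comes from the tissue, such as the smaller brain or levels further apart, from cutting, from fewer counts or from the angles was not tested. The organisms stay an open biological explanation, with 1 brain each and sections whose level in the brain the labels do not give.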

How the results depend on the processing

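The combinations of reversed sections, scaling to spike-ins and equal weights limited to strips above the minimum were chosen after seeing the data. Gene counts are given as percent of the genes tested under each setting, 11150 in the mouse and 10392 in the lizard unless the gene minimum changed, while changes by over 1.5 times were judged on the counts. Patterned mouse genes (28.87% as reported) stayed within 1.5 times the reported count under every alternative run, and lizard genes (7.55389%) under all but no strip minimum, which gave 27.6655%. Displaced genes became 38.5919% in the mouse and 1.80908% in the lizard with the fifth section reversed, 4.72646% and 0.962279% with the third and the fifth, and 11.9103% and 2.96382% with the fourth and the fifth, and 0 under the other combinations; leaving out 1 section gave 0 to 29.0045% and 0 to 1.32794%. With the fifth section reversed, the values without 1 section were 28.5202 to 42.8161% and 0.279061 to 20.2848%, without trend 24.1883% and 1.53002%, and with equal strip weights 0 and 0, or 29.5785% and 1.50115% over strips above the minimum. Narrower mouse genes (27.722%) were 30.8904% at a minimum of 5 counts, where fewer genes were tested, and wider mouse genes (25.8386%) 1.66816% with equal weights. In the lizard, narrower and wider genes (2.77136% and 1.08737%) were 0.712086% and 0.134719% with equal weights, 3.22926% and 1.17752% at a minimum of 5 counts, and 1.26059 to 6.36066% and 0.250192 to 4.06082% without 1 section. Equal weights give near-empty strips full weight; limited to strips above the minimum they gave 26.4843% and 19.6054% in the mouse and 2.80023% and 1.33757% in the lizard. The spread correlation was 0.00542225 at a minimum of 5 counts, −0.020335 by rank and 0.00633039 to 0.0624793 without 1 section, and the shift correlation 0.0199454 with equal weights and −0.122678 to 0.132717 without 1 section (0.0124297 without lizard section 45); with the fifth section reversed in both organisms the latter was 0.0869424, and 0.0900486 with the fourth of the lizard reversed too. The sign of the shift correlation can turn with the main axis, which was set anew in each setting. Without a strip minimum 7 mouse and 3 lizard lists varied together. Mouse spread values turned with equal weights to 0.019162 (S100b), 0.104151 (Itm2a), 0.25766 (Apod), 0.334908 (Igf2), 0.359846 (Dcn), 0.0412979 (Zbtb20), 0.0100106 (Tyrobp), −0.100276 (Lhx6) and −0.0883963 (Sst), and over strips above the minimum to 0.0362176 (Aldoc), 0.00331556 (Itm2a), 0.0231008 (Dcn) and −0.0133455 (Sst), and in the lizard RGS9 turned to −0.0516922 with equal weights. Apart from the smaller number of genes tested at a minimum of 5 counts, the cause was not tested. Values that passed in neither setting and changed sign were not counted as turned. No paired analysis was possible because replicate numbers follow the order of the records only. With 20242 to 523264 counts per mouse strip and 15938 to 553456 per lizard strip, simulated peaks of 0.5 on the log2 scale were mostly missed.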

Other observations

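Single genes differed in how concentrated their RNA was. Among other named mouse genes, Tac2 (46.1% ± 3.30 of its summed abundance in the richest 10% of strips, SD, n = 5), Spink8 (57.2% ± 7.76) and Igf2 (43.3% ± 3.98) were concentrated beyond the 95th percentile of 22.7% for 6761 genes, while mt-Co1 (13.9% ± 0.80) and Bsg (15.5% ± 0.73) lay under the median of 17.5%. In the lizard CARTPT (61% ± 6.83), PENK (45.1% ± 1.90) and PVALB (35.7% ± 4.70) lay beyond the 95th percentile of 24% for 6376 genes, while ITM2A (13.6% ± 1.89) and CAMK2A (15.1% ± 0.30) lay under the median of 18.4%. The medians and percentiles are those of genes with a mean of at least 5 counts per strip. Named list members need not meet that minimum, and low counts can raise such a share. No test was run on these shares.

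The extent of all RNA differed between the sections cut at different angles. Its SD along the strips was 2.21, 2.53, 2.57, 2.71 and 2.29 mm in the mouse sections from the first to the fifth angle, and 1.07, 1.44, 1.81, 1.59 and 1.23 mm in the lizard sections. An ellipse fitted to these values had its long axis at 92.4° in the mouse (SD 2.69 mm along it and 2.22 mm across it) and at 88.3° in the lizard (1.78 and 1.03 mm), with R² of 0.816 and 0.981 over 5 sections. With few residual degrees of freedom a high R² can arise by chance, and the fit was not tested. Each angle was a different section without a replicate, so the angle cannot be told apart from other differences between sections.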
